A study of Drosophila melanogaster with 10 samples.

How the data were processed

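Gene expression was measured in SL2 cells, a Drosophila melanogaster line established from embryos, on 10 Affymetrix arrays with 1 array per sample. Per the labels, cells were kept at 26°C, incubated with 10 µg of double-stranded RNA (dsRNA) and harvested after 5 days, and biotin-labelled cRNA was made from total RNA. The group of each array was taken from the sample labels: 4 arrays were mock-treated with dsRNA against eGFP, a sequence with no target in the fly, and 6 were treated with dsRNA against Tip60. The 6 arrays used 3 different dsRNAs with 2 arrays each, named here by their position in the Tip60 sequence as the labels give it: 1321-1618, 190-807 and 603-1116. The last 2 overlap by 205 nucleotides, so they are not fully independent reagents. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical in part. No batch or scan date was given in the sources used here.

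The deposited values are linear probe set signal intensities, 1 column per array. Per the submitters' processing notes they were made with GCOS 1.4, the Affymetrix operating software; the background correction and the way probes were combined are not given in the sources used here. The deposited intensity of each array was scaled: the 2% trimmed mean over all 18952 probe sets came to 1000 on each of the 10 arrays. This scaling ties every array to its own bright probe sets. If fewer or less abundant transcripts reach an array, its background and its spike-in controls come out higher after scaling, and probe sets near the background can rise with no change of their transcript. For this reason the changes reported below are relative to the trimmed mean of an array, not absolute amounts per cell. For arrays the number of samples limits the precision, here 2 arrays per dsRNA.

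Of the 18952 probe sets, 183 are Affymetrix controls and were kept out of the tests, which left 18769 fly probe sets. Signals were used as deposited, on the log2 scale, with no further normalization because the arrays already shared 1 trimmed mean. Probe sets below the 40th percentile of mean log2 signal, a signal of 34.5, were left out, and 11261 were tested. Gene names came from the platform annotation given with the series and were updated by Entrez identifier through a RefSeq table of the assembly Release 6 plus ISO1 MT. Of the fly probe sets 13647 had 1 gene symbol, 402 had several and 4720 had none; 13544 of those with 1 symbol matched the table by identifier. Probe sets with several genes or none were tested but not named. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed, and the table served only for names and for which genes neighbour each other. The probe sequences were not used here, so a probe set that also binds a paralog was not screened out.

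The main comparison fitted the 6 Tip60 RNAi arrays against the 4 eGFP RNAi arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and a probe set was called at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over all 11261. A fit with 4 group means gave each dsRNA against eGFP, each pair of dsRNAs, and an F-test of any difference among the 3 dsRNAs. Values measured once per array, such as the Tip60 signal or the mean of the spike-ins, were compared by a two-sided exact permutation test over the 210 splits of the 10 arrays into 6 and 4; 9 such measures were tested, and the smallest p that this test can give is 0.00476.

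Before the data were examined, 32 gene lists were fixed: subunits of the Tip60 complex, other chromatin regulators, cell cycle, metabolism, stress, immunity, signalling and markers of cell types. Of 535 members written as symbols, 4 matched no gene. Each gene entered by its brightest probe set. The 30 lists with at least 5 measured genes were tested with camera (limma), which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data. The muscle marker list had 3 measured genes and the list of replication-dependent histones had 0, so neither was tested. For each list its median change was also ranked among 10000 random lists of the same size matched on mean signal in 20 bins. Their genes were drawn singly, so this rank takes no account of correlation among the genes of a list.

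The genes named in the text followed a rule set before the data were examined. It took Tip60 and each called member of its complex, then the 12 probe sets with 1 gene that rose most and the 12 that fell most among those called and with all 6 Tip60 arrays on one side of all 4 eGFP arrays. From each list it took up to 2 called members that rose most and 2 that fell most, from each dsRNA the 2 that rose most and the 2 that fell most, and the 5 with the smallest p in the F-test. Any other gene named was chosen after its values were seen, as is said there.

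The comparisons of the 3 dsRNAs with eGFP share the same 4 control arrays, which by itself makes their changes alike. That share was estimated from 100 simulations of unchanged groups, and the overlaps were also computed after splitting the control arrays into pairs. The fits were tested on simulated data made from the real means and spreads with 67 probe sets changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among 11261. For the main comparison 59.7% of the probe sets changed 1.5-fold were recovered, 76.1% of those changed 2-fold and 81.8% of those changed 4-fold; all recovered ones had the right sign and 5.84% of the calls were false. For the F-test among dsRNAs, with the changes placed in the group of dsRNA 1321-1618, 52.2%, 68.7% and 74.2% were recovered at these folds, and 11.0% of the calls were false. Each of these was a single draw in which probe sets varied independently. Far fewer probe sets were changed in it than the 34.5% called in the real main comparison, so these shares need not hold for the real calls. In a simulation with 1 of 30 lists shifted, camera called that list and 0 of the other 29. Its genes varied independently, while the correlation estimated in the real data was 0.65 for cytoplasmic ribosomal proteins. It therefore cannot show how often correlated genes give a false list call.

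Alternatives fixed before the data were examined were quantile normalization, median centring, a floor at the 20th percentile, no filter and a filter at the 60th percentile (a signal of 188), no intensity trend, 4 group means, 5 pairs of arrays as a random block or averaged (2 eGFP pairs that share a leading number, and the 2 arrays of each of the 3 dsRNAs), the leading replicate number as a block, each dsRNA left out, each array left out, an estimated inter-gene correlation, and the mean of all probe sets of a gene. Cyclic loess, scaling to the hybridization spike-ins, scaling to the poly-A spike-ins and centring on the median of the probe sets above the 60th percentile were added after seeing the data, as was the Tip60 complex list without Tip60. Python 3.11.15 and matplotlib 3.10.9 drew the plots.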

Results

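Transcript levels were measured in SL2 cells, a macrophage-like Drosophila line, on 10 arrays. Tip60 is the histone acetyltransferase subunit of a chromatin remodelling complex that also exchanges histone variants. It was depleted by RNA interference for 5 days on 6 arrays, with 3 dsRNAs on 2 arrays each, and 4 arrays of cells treated with dsRNA against eGFP served as the mock control. The stated purpose was to find expression changes across the genome after loss of Tip60. Every array measured 18952 probe sets, and the trimmed mean signal was the same on all of them. The median signal was not: it lay between 55.6 and 72.1 on the eGFP arrays and between 78.6 and 110.1 on the Tip60 RNAi arrays. Arrays of 1 group correlated at 0.957 to 0.972 across probe sets, and eGFP with Tip60 RNAi arrays at 0.947 to 0.958. The first principal component (29.1% of the variance) separated the treatments, from −41.9 to −30.8 on the eGFP arrays and from 12.7 to 39.0 on the Tip60 RNAi arrays. The next one (11.4%) set replicate 1 of dsRNA 190-807 apart, at 57.0 against −15.7 to 3.55 on the other arrays.

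The Tip60 transcript itself fell with each dsRNA. Its signal was 1239 ± 103 (SD, n = 4) on the eGFP arrays, 281 ± 8.0 (n = 2) with dsRNA 1321-1618, 304 ± 135 (n = 2) with dsRNA 190-807 and 337 ± 64.1 (n = 2) with dsRNA 603-1116. These signals were 22.7%, 24.6% and 27.2% of the control mean. All 6 arrays lay below all 4 controls, with a mean log2 change of −2.04 (SE 0.15, adjusted p = 4.77e-08) and a two-sided exact permutation p of 0.00476, the smallest that the 210 splits allow. Where the probe set lies in the transcript relative to the 3 dsRNAs was not examined here.

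**Figure D1:**
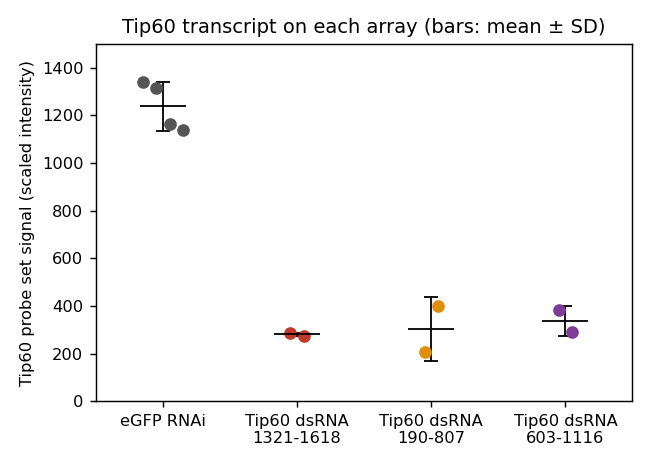
Signal of the Tip60 probe set (scaled intensity, linear axis from 0) on each array, as points, with the mean ± SD of each group. The 4 eGFP arrays average 1239 and the 3 dsRNAs average 281, 304 and 337 with 2 arrays each.

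mthl2, a receptor gene of the Methuselah family, rose 36.1-fold after Tip60 RNAi, from 106 ± 29.8 (SD, n = 4) to 3731 ± 429 (n = 6), a log2 change of 5.17 (SE 0.15, adjusted p = 3.51e-13). The C-type lectin gene lectin-24A rose from 22.2 ± 15.6 to 631 ± 85.2 (log2 change 5.10, SE 0.35). Log2 changes between 3.11 and 4.02 were found for CG34054, CG1208, CG10764, CG13937, the angiotensin-converting enzyme homolog Ance-5, CG43125, the aquaporin-like channel Eglp2, the cytochrome P450 Cyp4s3, the lamellocyte surface protein gene atilla and the scavenger receptor gene Sr-CIII. The tightest of these was CG43125, with 689 ± 9.19 on the eGFP arrays and 6825 ± 251 after Tip60 RNAi (log2 change 3.31, SE 0.05, adjusted p = 1.62e-16). lectin-24A, CG13937, Eglp2, Cyp4s3 and Sr-CIII lay below the filter level of 34.5 on average in the controls, so their folds start from signals near the background.

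The falls were smaller. The endoribonuclease gene EndoU fell most, from 382 ± 55.1 to 80.5 ± 25.3 (log2 change −2.30, adjusted p = 4.06e-06), and another probe set of the same gene gave −1.73. Next to Tip60 came CG12910 (−1.69), Cyp49a1 (−1.61), the light-activated calcium channel gene trp (−1.60), CG16888 (−1.54), the transcriptional corepressor gene nvy (−1.53), mthl15 (−1.49), Acsf2 (−1.49), CG4570 (−1.43) and CG31546 (−1.41). CG4570 fell from 1556 ± 38.9 to 578 ± 44.9 with an adjusted p of 1.68e-09. Cyp49a1 ended below the filter level, at a mean of 29.6, so the size of its fall is not exact. It lost its call in 8 of the 10 fits that left out 1 array (adjusted p 0.0603 to 0.111). The call of trp was lost without eGFP replicate 2-1 (adjusted p = 0.0696) or 3-2 (0.0576), and that of mthl15 without eGFP replicate 2-1, 2-2 or 3-2 (0.0663 to 0.0818).

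**Figure D2:**
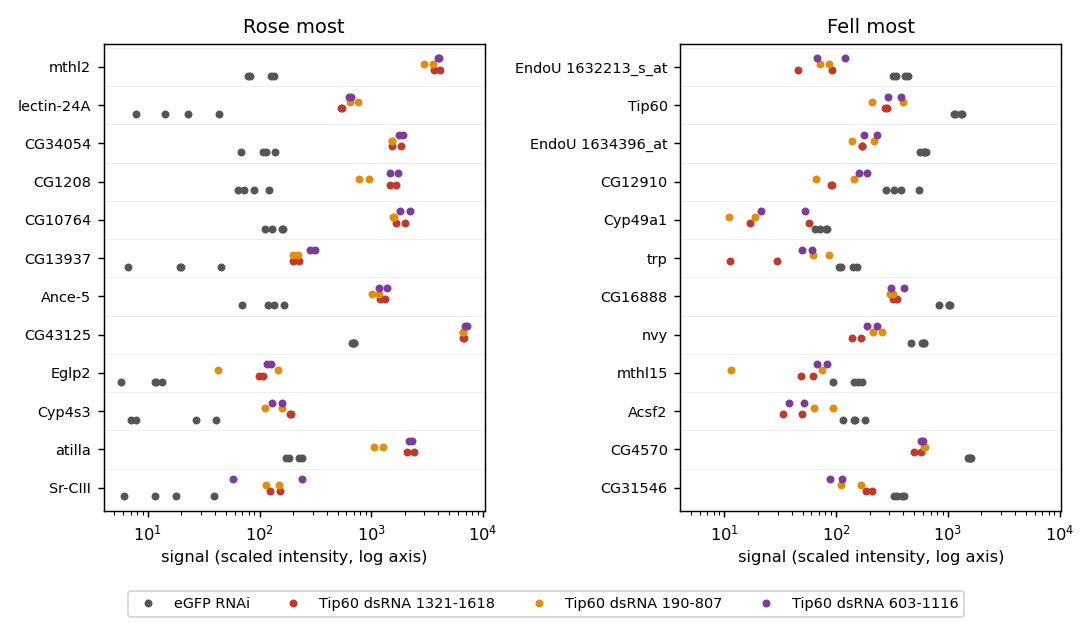
Signal (scaled intensity, log axis) of the 12 probe sets that rose most and the 12 that fell most, by the fixed rule; each point is 1 array, in grey for the 4 eGFP arrays and in colour for the 6 Tip60 RNAi arrays. In each of them all Tip60 RNAi arrays lie on one side of all eGFP arrays; mthl2 goes from 106 to 3731 on average and EndoU from 382 to 80.5.

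In all, 3885 of 11261 probe sets (34.5%) changed at an adjusted p under 0.05, 2002 higher and 1883 lower after Tip60 RNAi. The higher ones came from 1504 genes and the lower ones from 1652, with 6 genes in both. As deposited, changes of at least 2-fold were mostly rises, 522 against 37 falls, a split that other scalings reversed (below). Among the called probe sets 2739 had all Tip60 RNAi arrays on one side of all controls, 1316 higher and 1423 lower; chance separates 0.952% of probe sets, and 2862 were separated with or without a call. Leaving out 1 array gave between 3267 and 3971 calls.

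How many transcripts rose depended on brightness and on scaling. In the dimmest of 4 equal classes of the probe sets tested (signals 34.5 to 91.1) 259 rose and 10 fell, with a median log2 change of 0.49. In the brightest class 682 rose and 900 fell, with a median of −0.03. Control probe sets with no fly target shifted too: the hybridization spike-ins were higher by 0.55 on the log2 scale on the Tip60 RNAi arrays (exact permutation p = 0.0143, adjusted over 9 measures 0.0257), and the poly-A spike-ins by 0.76 (exact p = 0.00476, adjusted 0.0107). The 70 other non-fly controls were higher by 0.56 (exact p = 0.0381, adjusted 0.0571), and fly probe sets under the filter by 0.58 (exact p = 0.00476, adjusted 0.0107).

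The split of 51.5% higher calls in the main comparison was 44.9% after quantile normalization (1524 higher, 1873 lower) and 58.6% with arrays centred on brighter probe sets (2260 higher, 1599 lower). With arrays centred on their median it was 6.84% (401 higher, 5460 lower), with arrays scaled to the hybridization spike-ins 5.88% (295 and 4718) and with the poly-A spike-ins 3.21% (229 and 6898). These last 3 moved the median change of all probe sets to −0.43, −0.47 and −0.68, from 0.08 as deposited. They lower every log2 change by 1 constant (0.51, 0.55 and 0.76), so any smaller rise turns negative under them and no fall can turn. Such a flip follows from the scaling and tells nothing of the single gene. The same holds for each rise below that is given as negative or as a called fall under them. It counts neither for nor against that rise. After quantile normalization, cyclic loess and centring on brighter probe sets alike, the other 3 scalings, 1438 of the 2002 rises and 1547 of the 1883 falls kept their call and sign, and 310 of 522 rises and 35 of 37 falls of at least 2-fold. Their shifts of log2 changes ran from −0.61 to 0.069 (quantile normalization) and from −0.53 to 0.037 (cyclic loess), and were 0.036 throughout for brighter probe sets. Only the smallest falls could turn under them, so a kept fall shows a kept call and is a weaker check than a kept rise. Under all 6 scalings 210 rises kept call and sign, each of at least 2-fold. The constants set that limit in part, so a rise lost only by them is not thereby in doubt. The same holds for the counts under all 6 scalings given for lists below. The 559 changes of at least 2-fold became 324 after quantile normalization (239 higher, 85 lower), 345 after cyclic loess (264 and 81) and 210 under the stricter filter (186 and 24). With arrays centred on the median falls outnumbered rises (193 higher, 584 lower), as they did with the hybridization (178 and 728) and poly-A spike-in scalings (129 and 2038).

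**Figure D3:**
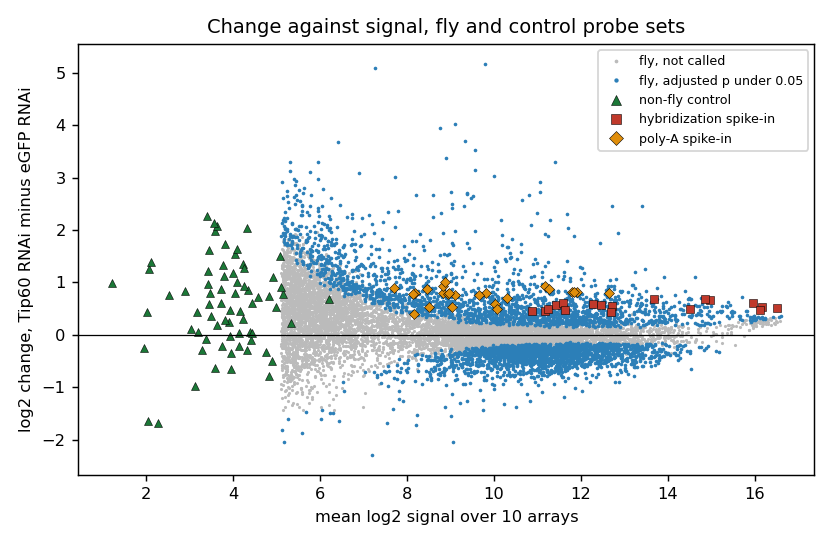
Log2 change (Tip60 RNAi minus eGFP RNAi) against mean log2 signal over the 10 arrays; points are fly probe sets above the filter, blue where called, and larger symbols are controls without a fly target. The poly-A spike-ins (0.76 on average), hybridization spike-ins (0.55) and other non-fly controls (0.56) lie above 0, as does the dim end of the fly probe sets.

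Genes of cell division fell as a group. Of 32 measured mitosis genes 23 fell and 2 rose (24 and 2 adjusted over the list alone), with a median log2 change of −0.52 (camera, adjusted p = 2.89e-09; 0.0491 with an estimated correlation). The centromeric histone gene cid fell from 709 ± 56.0 to 371 ± 69.5 (log2 change −0.95, adjusted p = 4.85e-05) and the condensin subunit gene glu by 0.77. The risers were the phosphatase gene twe (0.44) and the kinesin gene Klp10A (0.23). By the constant shifts both turned negative with arrays centred on the median or scaled to either spike-in, and Klp10A became a called fall with the poly-A spike-ins (adjusted p = 0.00104). Their calls were also lost in 8 and 4 of the 10 fits that left out 1 array, with adjusted p up to 0.118 and 0.112.

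Of 34 DNA replication genes 21 fell and 0 rose (the same counts adjusted over the list alone; median −0.32, camera adjusted p = 3.28e-08; 0.0327 with an estimated correlation). PolA2, a subunit of the polymerase that starts new strands, fell by 0.76 on the log2 scale and the sliding clamp gene PCNA by 0.71 (8625 ± 776 to 5256 ± 331). Among 14 modifiers of heterochromatin 8 fell and 0 rose (8 and 0 adjusted over the list alone; median −0.33, adjusted p = 0.000534; 0.0491 with an estimated correlation). The gene of heterochromatin protein HP1a fell by 0.52 and HP1b by 0.50. These 3 lists kept a negative median and their camera call under each setting tried. After quantile normalization, cyclic loess and centring on brighter probe sets 22 mitosis, 19 replication and 8 heterochromatin genes kept their called fall. Those scalings raise a log2 change by at most 0.069, so the sign of any larger fall was fixed and only the call could be lost. Among random lists of the same brightness the 3 medians stood at percentiles 0, 0 and 0.05.

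Genes for ribosome assembly, mitochondria and the proteasome fell as well, though none of these calls held with an estimated correlation. Of 19 ribosome biogenesis genes 14 fell and 2 rose (14 and 2 adjusted over the list alone; median −0.43, camera adjusted p = 2.75e-05; adjusted p = 0.123 with an estimated correlation). The snoRNP protein gene NHP2 fell by 0.78 and the RNA polymerase I subunit gene Polr1A by 0.58. Nop17l (0.47) and Non1 (0.31) rose. By the constant shifts both were negative with arrays centred on the median or scaled to either spike-in, Non1 as a called fall with the poly-A spike-ins (adjusted p = 0.00612). Of 69 mitochondrial ribosomal protein genes 44 fell and 0 rose (47 adjusted over the list alone; median −0.30, adjusted p = 3.89e-10; adjusted p = 0.106 with an estimated correlation), mRpS14 by 0.77 and mRpS18A by 0.63. Both medians stood at percentile 0 of random lists of the same brightness.

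Of 22 oxidative phosphorylation genes 16 fell and 0 rose (17 adjusted over the list alone; median −0.30, adjusted p = 7.41e-07; adjusted p = 0.158 with an estimated correlation), with ATPsynB at −0.50 and COX5B at −0.48. Of 28 proteasome subunit genes 21 fell and 0 rose (22 adjusted over the list alone; median −0.27, adjusted p = 1.48e-07; adjusted p = 0.158 with an estimated correlation), with Prosbeta5 at −0.55 and Rpn5 at −0.45. Both medians stood at percentile 0.01 of matched random lists. That rank takes no account of inter-gene correlation, which was estimated at 0.28 and 0.26 for these lists. The aminoacyl-tRNA synthetases, which charge tRNAs, had 9 of 29 genes lower and 0 higher (9 and 0 adjusted over the list alone; median −0.12, adjusted p = 0.0157; adjusted p = 0.322 with an estimated correlation), with IleRS at −0.49 and HisRS at −0.47. Their median stood at percentile 15.03 of matched random lists. That call was also lost after quantile normalization (adjusted p = 0.0765), cyclic loess (0.0584), under the stricter filter (0.111), with 4 group means (0.0744) and with the pairs of arrays as a random block (0.0664) or averaged (0.0553).

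Among genes of the RNA interference machinery piwi and aub fell. Both act in the piRNA pathway, which silences transposons. piwi went from 2762 ± 266 to 1285 ± 249 (log2 change −1.12, SE 0.12, adjusted p = 3.26e-06) and aub from 4262 ± 232 to 2448 ± 156 (−0.80, SE 0.06, adjusted p = 9.36e-08). Of the 11 measured genes of this list 5 fell and 0 rose (5 and 0 adjusted over the list alone; median −0.04, mean −0.25, camera adjusted p = 0.0331; adjusted p = 0.123 with an estimated correlation). The list's call was lost after quantile normalization (adjusted p = 0.0784), cyclic loess (0.0584) and under the stricter filter (0.131), and its median stood at the 46.6th percentile of random lists of the same brightness. Its 5 falls kept their call after quantile normalization, cyclic loess and centring on brighter probe sets.

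The Polycomb and trithorax genes, which maintain silent and active chromatin, had 7 of 25 genes lower and 1 higher (8 and 1 adjusted over the list alone; median −0.12, adjusted p = 0.0331; adjusted p = 0.211 with an estimated correlation). ash2 fell by 0.50 on the log2 scale and brm, the ATPase of a remodelling complex, by 0.49. Psc rose by 0.54 as deposited, and was −0.22 with the poly-A spike-in scaling. The median stood at the 21.8th percentile of matched random lists. The list's call ended after quantile normalization (adjusted p = 0.307) and cyclic loess (0.187), under the stricter filter, with 4 group means, with the pairs of arrays as a random block or averaged, and without dsRNA 1321-1618 or 190-807. It ended too without eGFP replicate 2-2 (0.0502), replicate 2 of dsRNA 1321-1618 (0.0594) or replicate 1 of dsRNA 190-807 (0.0794).

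Among lists that rose, markers of hemocytes, the fly's blood cells, stood first. Of 23 measured markers 21 rose and 1 fell (21 and 1 adjusted over the list alone; median 0.44, camera adjusted p = 2.43e-09; adjusted p = 0.0656 with an estimated correlation). The list's median was −0.06 with arrays centred on the median, −0.10 with the hybridization and −0.32 with the poly-A spike-in scaling, while camera still placed it above other genes; as deposited it stood at percentile 100 of matched random lists. Of the 21 rises 17 kept call and sign after quantile normalization, cyclic loess and centring on brighter probe sets, and 4 under all 6 other scalings. atilla rose from 207 ± 31.8 to 1889 ± 575 and NimC1, a phagocytosis receptor, from 2416 ± 191 to 13362 ± 1592 (log2 change 2.46, SE 0.08, adjusted p = 2.69e-12). PPO1, a prophenoloxidase of crystal cells, fell by 0.38. The 23 measured markers, of 25 listed, were those above the filter in these SL2 cells.

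Immune genes rose too: 14 of 24 were higher and 1 lower (15 and 1 adjusted over the list alone; median 0.39, adjusted p = 6.81e-06; adjusted p = 0.123 with an estimated correlation). Their median was −0.11, −0.15 and −0.37 under the 3 scalings just named, with the camera call kept, and of the 14 rises 14 kept call and sign after quantile normalization, cyclic loess and centring on brighter probe sets, and 3 under all 6 other scalings. As deposited the median stood at percentile 100 of matched random lists. The antifungal peptide gene Drs rose from 1438 ± 131 to 5979 ± 1179.8 (log2 change 2.04) and the antibacterial peptide gene AttD from 644 ± 90.6 to 2283 ± 343 (1.82). Fadd, an adaptor of the Imd pathway, fell by 0.26; its call was lost without eGFP replicate 2-2 (adjusted p = 0.0977) or 3-2 (0.0837).

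Cytochrome P450 genes, which oxidize hormones and foreign compounds, had 14 of 57 members higher and 4 lower (14 and 3 adjusted over the list alone; median 0.19, adjusted p = 0.0152; adjusted p = 0.0805 with an estimated correlation). The median stood at the 51.4th percentile of random lists of the same brightness. It was −0.31, −0.35 and −0.57 with arrays centred on the median or scaled to the hybridization or poly-A spike-ins, and the call was lost after quantile normalization (adjusted p = 0.166) and cyclic loess (0.135). Of the 14 rises 9 kept call and sign after quantile normalization, cyclic loess and centring on brighter probe sets, and 4 under all 6 other scalings; 3 of the 4 falls kept theirs under those 3. The rule named Cyp4s3 (log2 change 3.29) and Cyp6a2 (2.79) as rises and Cyp49a1 (−1.61) and Cyp4d1 (−1.48) as falls. Cyp4s3 and Cyp6a2 start from control means of 20.7 and 27.5 and Cyp49a1 ends at 29.6, below the filter level, so these sizes are not exact. Cyp4d1 lost its call in 8 of the 10 fits that left out 1 array (adjusted p 0.0625 to 0.114).

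Cytoplasmic ribosomal protein genes had 9 of 40 members higher and 1 lower (6 and 1 adjusted over the list alone; median 0.24, adjusted p = 0.00458; adjusted p = 0.686 with an estimated correlation). The median was −0.02 after quantile normalization, −0.26 with arrays centred on the median and −0.30 and −0.52 with the spike-in scalings, and no call held under these, nor with 4 group means (adjusted p = 0.0958) or the pairs of arrays as a random block (0.057). Without eGFP replicate 2-1 the adjusted p was 0.0898. As deposited the median stood at the 98.4th percentile of matched random lists, a rank that takes no account of the correlation among these genes. Of the 9 rises 3 kept call and sign after quantile normalization, cyclic loess and centring on brighter probe sets. The count under all 6 other scalings was 0, which the constant shifts set, as the largest called rise of the list was 0.79. Among its extreme members RpS5b (0.79), whose call was lost after quantile normalization (adjusted p = 0.0738), is a ribosomal protein paralog; qm (0.65), a synthase of isoprenoid precursors, and RpLP0-like (−0.53), a ribosome assembly factor, are not subunits of the ribosome.

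**Figure D4:**
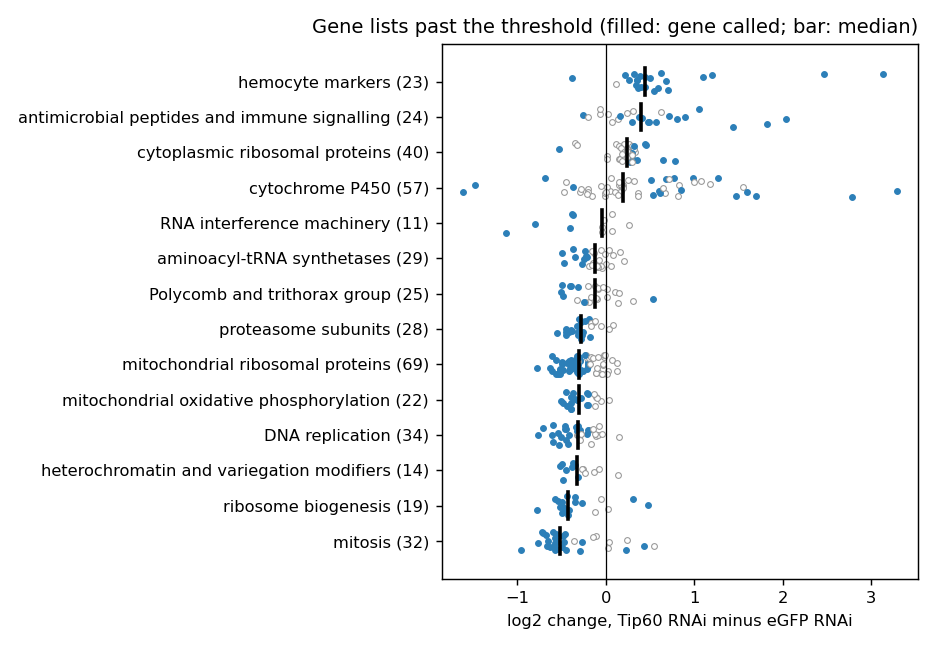
Log2 change (Tip60 RNAi minus eGFP RNAi, values as deposited) of each measured gene in the 14 lists past the threshold, with the number of genes in brackets; filled points are called genes and black bars are medians. Medians run from −0.52 (mitosis) to 0.44 (hemocyte markers); those of the 4 lists at the top turn negative with arrays centred on the median or scaled to spike-ins.

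In the list of Tip60 complex subunits, which holds Tip60 itself, 5 of 13 genes fell and 1 rose (7 and 2 adjusted over the list alone; median −0.15, adjusted p = 0.133). The list passed the threshold with arrays centred on the median (adjusted p = 0.0301), scaled to hybridization (0.014) or poly-A spike-ins (0.00792), and with no filter (0.0356). Without Tip60, a test chosen after seeing the data, the other 12 subunits had a median of −0.12 (adjusted p = 0.389), and none of these 4 settings gave a call (0.111 to 0.22). The ATPase gene rept fell from 4897 ± 251 to 3508 ± 226 (log2 change −0.48), MrgBP by 0.47, Gas41 by 0.26 and the histone variant gene His2Av by 0.15. The ATPase gene dom rose by 0.41, was −0.09 with arrays centred on the median and became a called fall with the poly-A spike-ins (adjusted p = 0.0336). The call of Gas41 was lost without eGFP replicate 3-1 (adjusted p = 0.0561), and that of His2Av in 8 of the 10 fits that left out 1 array (0.0691 to 0.138).

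Of 19 other acetyltransferase and deacetylase genes 4 fell and 2 rose (4 and 2 adjusted over the list alone; adjusted p = 0.634). The deacetylase gene HDAC1 fell by 0.67 and Hat1 by 0.47, while HDAC4 (0.58) and Ada2b (0.40) rose. By the constant shift of the poly-A spike-in scaling both rises turned negative, Ada2b as a called fall (adjusted p = 0.0365). In the DNA damage list 4 of 23 genes fell and 3 rose (4 and 3 adjusted over the list alone; adjusted p = 0.833): the checkpoint kinase gene grp fell by 0.55 and the mismatch repair gene Msh6 by 0.54. Gadd45 rose by 0.78, a call lost with the constant shifts of the median and spike-in scalings. By these shifts p53 (0.29) was negative, a called fall with poly-A spike-ins (adjusted p = 0.00425). Of 10 apoptosis genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.564). The receptor gene wgn fell by 0.74, while the caspase gene Dronc (0.34) and the ligand gene egr (0.26) were higher as deposited and negative with the median and spike-in scalings. With poly-A spike-ins both were called falls (adjusted p = 0.00965 and 0.00255).

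In glycolysis 3 of 9 genes fell and 2 rose (3 and 2 adjusted over the list alone; adjusted p = 0.564). Pgk fell by 0.76 and Gapdh1 by 0.56; Hex-A (0.61) and Ald1 (0.42) were higher, and negative with the poly-A spike-in scaling, Ald1 as a called fall (adjusted p = 0.0442). Of 10 lipid synthesis genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.733). eas (0.39) and SREBP (0.30) were higher and negative with the median and spike-in scalings, and called falls with poly-A spike-ins (adjusted p = 0.0224 and 0.00476). bbc (−0.23) and SCAP (−0.17) lost their calls in 7 and 4 of the 10 fits that left out 1 array, with adjusted p up to 0.162 and 0.0818. Of 11 heat shock genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.409). Hsp26 (0.62) and the endoplasmic reticulum chaperone Hsc70-3 (0.54) rose, and were negative by the constant shift of the poly-A spike-in scaling. Hsp60A fell by 0.31, and Hsf (−0.21) lost its call in 4 of the 10 such fits (adjusted p up to 0.0844).

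In the glutathione transferase list 10 of 28 genes fell and 6 rose (10 and 7 adjusted over the list alone; median 0.05, adjusted p = 0.542). Its camera direction was downward, against the sign of its median. GstD7 fell from 3072 ± 283 to 1573 ± 27.3 (log2 change −0.96) and GstT3 by 0.55. GstD10 (0.65) was negative with the poly-A spike-in scaling, and GstD6 (0.94) lost its call without eGFP replicate 2-2 or 3-2 or replicate 2 of dsRNA 1321-1618 (adjusted p 0.0541 to 0.0654). The change of GstD6 shrank, with no call, after quantile normalization (0.50, adjusted p = 0.255), cyclic loess (0.55, 0.214), median centring (0.43, 0.26) and scaling to hybridization (0.39, 0.373) or poly-A spike-ins (0.18, 0.683). Of 19 autophagy and lysosome genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.206). The kinase gene Atg1 (0.62) and the cargo receptor gene ref(2)P (0.39) were higher and turned negative with the poly-A spike-in scaling, ref(2)P as a called fall (adjusted p = 0.0238). Atg4a fell by 0.26.

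Among signalling lists, Wnt, Hedgehog and Dpp genes had 4 of 13 members lower and 1 higher (4 and 2 adjusted over the list alone; median −0.13, mean 0.00, adjusted p = 0.389). The ligand gene dpp rose from 344 ± 85.1 to 688 ± 78.1 (log2 change 1.03), a call lost with the hybridization (adjusted p = 0.0655) and poly-A spike-in scalings (0.205), and its receptor genes tkv and put fell by 0.51 and 0.38. Of 9 Notch genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.564). The protease gene kuz (0.78) lost its call with the median and spike-in scalings, and the coactivator gene mam (0.57) was negative with the poly-A spike-in scaling. E(spl)m3-HLH (−0.34) lost its call in 6 of the 10 fits that left out 1 array (adjusted p up to 0.0993).

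Of 15 ecdysone response genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.733). The transcription factor gene br (0.66) was higher and the receptor gene Hr78 lower (−0.56); br was negative with the poly-A spike-in scaling. tai (0.49) was negative with the median and spike-in scalings and lost its call without eGFP replicate 2-1 (adjusted p = 0.0815) or 3-1 (0.0784), as MsrA (−0.34) did without eGFP replicate 2-2 (0.0749) or 3-2 (0.0533). In dosage compensation msl-1 (−0.31) was the 1 gene called of 6 (1 adjusted over the list alone; list adjusted p = 0.815), lost without eGFP replicate 3-1 (0.0531) or 3-2 (0.086). In the JAK-STAT list 1 of 5 genes fell, the SUMO ligase gene Su(var)2-10 (−0.31; 1 adjusted over the list alone; list adjusted p = 0.894).

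Markers of other cell types were measured as a check on the line. Of 6 neuronal and glial genes 1 was called (0 adjusted over the list alone; list adjusted p = 0.815), brp at 0.31, which was negative with the median and spike-in scalings and a called fall with poly-A spike-ins (adjusted p = 0.0215). Of 5 fat body and cuticle genes 1 was called (1 adjusted over the list alone; list adjusted p = 0.543), Edg78E, from 21.3 ± 11.0 to 63.0 ± 17.0, a call lost after quantile normalization (adjusted p = 0.163) and with the median and spike-in scalings. brp and Edg78E lost their calls in 7 and 4 of the 10 fits that left out 1 array, with adjusted p up to 0.0912 and 0.0754. The 3 measured muscle genes, too few to test as a list, had log2 changes of 0.10 (sls), −0.21 (Act79B) and 0.90 (Mlc1), and none passed the threshold.

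Calls of single genes named above also ended under further settings. After quantile normalization and cyclic loess twe (adjusted p = 0.46 and 0.292), bbc (0.0519 and 0.0617), Hsf (0.0995 and 0.0628) and brp (0.167 and 0.141) lost theirs, Fadd after the former (0.0635) and Edg78E after the latter (0.136). Centring on brighter probe sets ended those of Cyp49a1, Fadd, Hsf, E(spl)m3-HLH, SCAP, bbc and His2Av (adjusted p 0.0521 to 0.14). With no filter those of GstD6, SCAP, E(spl)m3-HLH, brp, bbc, Cyp49a1, Cyp4d1, twe and His2Av ended (0.0502 to 0.0954), and with no intensity trend those of His2Av, mthl15, brp, Klp10A, Fadd, tai, E(spl)m3-HLH and bbc (0.0542 to 0.118). The floor ended that of His2Av (0.0508), and 4 group means those of twe (0.0519) and His2Av (0.0577).

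With the 5 pairs of arrays as a random block Cyp49a1, bbc and His2Av missed the threshold (adjusted p 0.0501 to 0.053), and with the pairs averaged Hsf, brp, Gas41, Edg78E, twe, msl-1, SCAP, Cyp49a1, Cyp4d1, E(spl)m3-HLH and His2Av did (0.0501 to 0.1). Without dsRNA 1321-1618 the calls of msl-1, Hsf, Su(var)2-10, Edg78E, Fadd, SCAP, His2Av, twe, GstD6 and brp ended (0.0509 to 0.135). Without dsRNA 190-807 those of tai, msl-1, Edg78E, Cyp49a1, Cyp4d1 and E(spl)m3-HLH did (0.0519 to 0.16), and without dsRNA 603-1116 those of SCAP, E(spl)m3-HLH, Edg78E, twe, Hsf, tai, Klp10A, Cyp4d1, His2Av and bbc (0.0645 to 0.229). The constant shifts of median centring and the hybridization spike-ins ended the calls of RpS5b, qm, br, GstD10, Hsp26, Atg1, Hex-A, HDAC4 and mam (0.252 to 0.951), and median centring those of Hsc70-3 (0.841) and Psc (0.86). RpS5b was not called with poly-A spike-ins either (0.938).

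Each dsRNA was also compared with eGFP by itself. dsRNA 1321-1618 changed 2671 probe sets (1255 higher, 1416 lower), dsRNA 190-807 changed 2492 (1222 and 1270) and dsRNA 603-1116 changed 3060 (1515 and 1545). By the fixed rule mthl2 and lectin-24A were the 2 named rises with each of them; mthl2 had log2 changes of 5.24, 4.99 and 5.29, and lectin-24A of 4.88, 5.27 and 5.14. The 2 falls that the rule named with each dsRNA ended below the filter level of 34.5 on at least 1 of its arrays, so their sizes are not exact. With dsRNA 1321-1618 they were the RNA-binding protein gene larp (−3.17, adjusted p = 2.38e-05) and CG15820 (−2.81, adjusted p = 0.0173). With dsRNA 190-807 they were the chitin-binding protein gene obst-A (−3.33, adjusted p = 0.0254) and CG4362 (−2.65, adjusted p = 0.0402), and with dsRNA 603-1116 SelR (−3.02, adjusted p = 0.000533) and the ion channel gene ppk31 (−2.96, adjusted p = 0.000591). Of these 6 genes the F-test among dsRNAs called larp alone. obst-A stood at 1.80 on replicate 1 of dsRNA 190-807, against 74.0 to 160.1 on the other Tip60 RNAi arrays.

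These counts rest on 2 arrays each and on the scaling. Without its replicate 1 dsRNA 1321-1618 gave 1507 calls, and dsRNA 603-1116 gave 1714 without its replicate 1 and 1864 without its replicate 3. With arrays centred on the median the splits were 317 higher and 3545 lower, 274 and 3992, and 237 and 5698 for the 3 dsRNAs in the order above. With hybridization spike-ins they were 150 and 1096, 111 and 1127, and 142 and 4037, and with poly-A spike-ins 175 and 6189, 195 and 5399, and 120 and 6860.

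The changes of the 3 dsRNAs overlapped. All 3 called 835 probe sets higher and 873 lower. In opposite directions 4 were called by a pair of dsRNAs. The pair 1321-1618 and 190-807 shared 903 rises and 955 falls, where independent lists of these sizes would share 136 and 160. Unchanged groups against the same controls shared 0 and 0.01. Groups without change give few calls to share, so this does not size the part of the overlap due to shared controls. The pair 1321-1618 and 603-1116 shared 1039 and 1116 (independent lists 169 and 194), and the pair 190-807 and 603-1116 shared 975 and 1019 (164 and 174). With the control arrays split so that no array served both dsRNAs, the pairs in this order shared 568 to 638, 689 to 739 and 633 to 691 rises, and 520 to 578, 647 to 719 and 582 to 632 falls.

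Log2 changes correlated across probe sets, which are not independent replicates, at 0.66, 0.69 and 0.67 for these pairs, against 0.33 in each case for unchanged groups with shared controls. Their covariances were 0.26, 0.29 and 0.29 against 0.06, which leaves differences of 0.20, 0.23 and 0.23. With split controls the correlations were 0.39 to 0.44, 0.42 to 0.49 and 0.43 to 0.46.

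Few differences among the 3 dsRNAs were called: the F-test called 4 probe sets. At an unadjusted p under 0.05 there were 1025, more than chance alone gives among 11261. With 2 arrays per dsRNA further differences may have been missed, so the low count does not show that the dsRNAs acted alike. Idgf2, a chitinase-like growth factor gene, had signals of 52079 ± 6291 with dsRNA 1321-1618, 25078 ± 400.4 with 190-807 and 29516 ± 141 with 603-1116 (n = 2 each, adjusted p = 0.00557), against 33744 ± 1946 on the eGFP arrays. larp stood at 23.5 ± 5.46 with dsRNA 1321-1618 against 189 ± 77.7 and 216 ± 3.90 with the others (adjusted p = 0.0105), and 215 ± 61.3 on the eGFP arrays. CG3740 was 103 ± 6.00 with dsRNA 1321-1618, 298 ± 35.0 with 190-807 and 412 ± 73.9 with 603-1116 (adjusted p = 0.0105), against 241 ± 25.2 on the eGFP arrays. The lipid kinase gene Pi4KIIIalpha was 3403 ± 166 with dsRNA 190-807, 2021 ± 245 with 1321-1618 and 2231 ± 95 with 603-1116 (adjusted p = 0.0356), against 1879 ± 134 on the eGFP arrays. The fifth probe set had no gene name and missed the threshold (adjusted p = 0.0619).

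By pairs, 5 probe sets differed between dsRNAs 1321-1618 and 190-807, 3 between 1321-1618 and 603-1116, and 0 between 190-807 and 603-1116 (limma, 950 at an unadjusted p under 0.05). The F-test count was 14 without replicate 1 of dsRNA 190-807, 8 without its replicate 3 or without eGFP replicate 3-2, 1 without either array of dsRNA 603-1116 and 0 without replicate 2 of dsRNA 1321-1618. Between 1321-1618 and 190-807 the count was 56 without replicate 1 of the latter, 10 without its replicate 3 or eGFP replicate 3-2 and 1 without either array of 603-1116. Between 1321-1618 and 603-1116 it was 12 without replicate 1 of the former, and 0 without its replicate 2 or either array of the latter. Between 190-807 and 603-1116 it was 44 without replicate 3 of the former and 1 without its replicate 1 or eGFP replicate 3-1 or 3-2. Without the intensity trend the F-test called 0 probe sets.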

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

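The tests of the dim probe sets and of the spike-ins were chosen only after the results were seen; the count of other splits was planned before.

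The 3885 probe sets that changed after Tip60 RNAi exceed what chance splits of the arrays give. Of 100 splits of the 10 arrays into 6 and 4, the real one included, 1 gave as many, the real one. That is the smallest share that 100 splits can give, and it argues against a chance split as the cause. Every other split mixed both treatments, so a technical difference between arrays that ran along with treatment was not tested. In such splits any real change counts as spread and lowers the calls, so their counts do not show how many of the 3885 may be false. The highest other count was 211, in a split that put 2 Tip60 RNAi arrays among the 6 with all 4 eGFP arrays.

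Dim probe sets were higher on the Tip60 RNAi arrays, and so were controls with no fly target, by 0.56 on the log2 scale for the 70 non-fly controls. If the scaling of each array raised its background, fly probe sets should rise as much as controls of the same signal. The median difference was 0.047 (95% bootstrap interval −0.25 to 0.33), an interval that holds the value this explanation predicts. Only the 67 controls below the filter level of 34.5 were used. The result therefore does not reach the dim rises called in the main comparison, at signals of 34.5 to 91.1. Genes near the detection limit that became expressed were also sought, as probe sets over 4-fold higher with no overlap of arrays. They made up 1.62% of 8078 dim fly probe sets and 0 of 66 controls, which allows up to 5.44%. With so few controls the shares cannot be told apart (one-sided Fisher's exact p = 0.341). Single genes are not judged by this comparison of shares, and 40 of these 131 probe sets were also called in the main comparison. The 131 probe sets may hold both kinds.

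The spike-in transcripts, bacterial RNAs added as controls, were higher on the Tip60 RNAi arrays too: by 0.55 for those added at hybridization and by 0.76 for the poly-A spike-ins added to the RNA before labelling. Less labelled fly cRNA on the array would raise only the former, so it is argued against as the whole cause by the shift of the latter (exact permutation p = 0.00476). A smaller poly-adenylated share of the total RNA, which would be a biological change, predicts a larger shift of the poly-A spike-ins. The difference was 0.21 (exact permutation p = 0.324), so this cannot be told apart from equal shifts with 10 arrays. It may also be that unequal amounts of spike-in were added; no amounts are given in the sources used here.

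In 11 groups of arrays 1 array stood far from the rest, among 250 groups tested, where chance alone gives about 1 in 20, or 12.5; 3 of the 11 were on replicate 1 of dsRNA 190-807. On the eGFP arrays the gap to the nearest array was 0.837 of the range for dom (2876 on replicate 2-1 against 2434 to 2501), 0.909 for CG16888 (829 on 2-2 against 1021 to 1043) and 0.834 for nvy (469.99 on 2-2 against 587 to 614). It was 0.873 for brp (544 on 3-1 against 484 to 491) and 0.856 for CG3740 (279 on 3-2 against 224 to 231).

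On the Tip60 RNAi arrays the gap was 0.684 for Eglp2 (42.9 on replicate 3 of dsRNA 190-807 against 99.3 to 146), 0.759 for Msh6 (2538 on replicate 3 of dsRNA 603-1116 against 2334 to 2381) and 0.662 for eas (5704 on replicate 1 of dsRNA 603-1116 against 6883 to 7577). On replicate 1 of dsRNA 190-807 it was 0.731 for mthl15 (11.5 against 48.5 to 82.5), 0.674 for IleRS (7253 against 4619.6 to 5350.3) and 0.828 for obst-A (1.80 against 74.0 to 160.1).

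The effect of Tip60 RNAi differed among the 3 dsRNAs for Idgf2 (F-test adjusted p = 0.00557), larp (0.0105), CG3740 (0.0105) and Pi4KIIIalpha (0.0356).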

How the results depend on the processing

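Cyclic loess, both spike-in scalings, centring on brighter probe sets and the Tip60 complex list without Tip60 were chosen after seeing the data. Over the 27 settings run for it the Tip60 transcript stayed lower and past the threshold. Outside the values below and the list medians in the report, called results kept their direction, and the cause was not tested. Of 121 named genes and lists with a call 13 lost it after quantile normalization, 31 with median centring (15 by turning negative, below), 32 with hybridization spike-ins (18 so), 20 with poly-A spike-ins (13 so), 10 after cyclic loess, 24 with the replicate block (below), 5 to 14 without 1 array and 1 to 13 under the other settings that tested them all. Under the first 2 the median of cytoplasmic ribosomal proteins turned negative too. The list of Tip60 complex subunits gained one under 4 settings, and without Tip60 under none of them (adjusted p 0.111 to 0.22). The main count of 3885 became 5861 with median centring and 7127 with poly-A spike-ins (median change of all probe sets −0.43 and −0.68), and the 559 changes of at least 2-fold became 324 (quantile), 345 (cyclic loess), 906 (hybridization spike-ins), 2167 (poly-A spike-ins) and 210 (stricter filter, fewer probe sets tested). The 14 lists became 9 after quantile normalization and 3 with an estimated correlation. Against eGFP, dsRNA 1321-1618 went from 2671 to 1246 (hybridization) and 6364 (poly-A), 190-807 from 2492 to 4266 (median), 1238 (hybridization) and 5594 (poly-A), and 603-1116 from 3060 to 5935 (median) and 6980 (poly-A). The F-test count of 4 became 10 (poly-A), 8 (no filter) and 0 (no trend). Between 1321-1618 and 190-807 the count of 5 became 3 (median, hybridization), 10 (floor), 9 (stricter filter) and 0 (no trend), between 1321-1618 and 603-1116 the count of 3 became 1 (no trend), and between 190-807 and 603-1116 the count of 0 became 4 (median), 3 (hybridization), 8 (poly-A) and 2 (no filter). Leaving out 1 array gave 1507 to 2891, 1789 to 2466 and 1714 to 3289 calls for the 3 dsRNAs against eGFP, 0 to 14 for the F-test, and 1 to 56, 0 to 12 and 0 to 44 for the pairs; a dsRNA left with 1 array is assumed to vary like the other groups.

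Small rises turned negative under 3 scalings that lower every log2 change by 1 constant (0.51, 0.55 and 0.76 in the order below), so the flips tell nothing of single genes. With median centring log2 changes were dom −0.094, Ada2b −0.11, twe −0.070, Klp10A −0.28, p53 −0.22, Dronc −0.17, egr −0.24, Ald1 −0.086, eas −0.12, SREBP −0.21, Nop17l −0.030, Non1 −0.20, brp −0.19, tai −0.015 and ref(2)P −0.12. With hybridization spike-ins they were dom −0.14, Ada2b −0.15, Psc −0.0072, twe −0.11, Klp10A −0.32, p53 −0.26, Dronc −0.21, egr −0.28, Ald1 −0.13, eas −0.16, SREBP −0.25, Nop17l −0.072, Non1 −0.24, Hsc70-3 −0.0040, brp −0.23, tai −0.057 and ref(2)P −0.16, with a median of −0.30 for cytoplasmic ribosomal proteins. With poly-A spike-ins they were dom −0.35, HDAC4 −0.18, Ada2b −0.36, Psc −0.22, twe −0.32, Klp10A −0.53, p53 −0.47, Dronc −0.42, egr −0.50, Hex-A −0.15, Ald1 −0.34, eas −0.37, SREBP −0.46, Nop17l −0.29, Non1 −0.45, Hsp26 −0.14, Hsc70-3 −0.22, brp −0.45, mam −0.19, br −0.10, tai −0.27, Atg1 −0.14, ref(2)P −0.37, qm −0.11 and GstD10 −0.11. By that constant 12 of them passed the threshold as falls, as the report says beside each.

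A check of arrays from different groups gave no sign that those with the same leading replicate number share more than it. Deviations from the group means correlated at −0.03 to 0.03 over 10 pairs of arrays with the same number and at −0.05 to 0.05 over 26 other pairs. Both arrays of a dsRNA deviate as mirror images, so these pairs are not independent and the check is weak. Signals of eGFP arrays correlated at 0.966 to 0.968 with the same number and at 0.964 to 0.972 with different numbers. With the leading number as a replicate block the main comparison gave 2785 calls (1374 higher, 1411 lower) and 10 lists. Number 1 is on Tip60 RNAi arrays only, replicate 1 of each dsRNA. These arrays add nothing to the change estimated with the block, so the calls lost under it also reflect fewer arrays. The lists of Polycomb and trithorax genes (adjusted p = 0.0723), RNA interference (0.0564), cytoplasmic ribosomal proteins (0.236) and aminoacyl-tRNA synthetases (0.0925) lost their call, and Tip60 stood at −1.96. The rest of the 24 calls lost with the block were of single genes, which are not listed here. For dsRNAs 190-807 and 603-1116, fitted on their 4 arrays, the block gave 10 calls.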

Other observations

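Genes that rose at least 2-fold in the values as deposited lay next to each other more often than random assignment gives. The neighbouring pairs named here were chosen after their values were seen. CG34054 (log2 change 4.02) lies beside the aquaporin gene Drip (3.09), the scavenger receptor gene Sr-CIII (3.11) beside its paralog Sr-CI (1.20), CG5321 (3.01) beside the axon guidance gene NetB (2.08) and Cyp4s3 (3.29) beside drd (1.49). The gustatory receptor genes Gr93b (1.23), Gr93c (1.32) and Gr93d (1.12) form a run with glec (1.39).

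These tests were planned before their results were seen. They used values as deposited and were not repeated under other scalings, on which the set of such rises depends. As deposited 522 probe sets rose at least 2-fold, 246 of them in the dimmest of the 4 classes of signal. After quantile normalization 239 did. Of 5686 pairs of neighbouring measured genes, in the order of the assembly Release 6 plus ISO1 MT, 28 had both genes at least 2-fold higher, against a mean of 8.94 in 10000 random assignments (95% of them 4 to 15; one-sided permutation p = 0.0001, the smallest they can give). Overlapping genes or shared probe sets are argued against as the whole cause, since 21 of 3372 pairs remained without them against a mean of 5.42 (permutation p = 0.0001). Dim genes that cluster and rise together are argued against too, since assignments within 10 classes of mean signal gave a mean of 9.33 (permutation p = 0.0001). Neighbouring genes may respond together to loss of Tip60, as a hypothesis; cross-hybridization between neighbouring paralogs stays open, because probe sequences were not used here.

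The 3 control probe sets for 18S ribosomal RNA ranged from 9.72 to 14.8 in mean log2 signal over the arrays, with a difference of −2.0 between Tip60 RNAi and eGFP arrays (exact permutation p = 0.0762). Arrays of 1 group that share a leading number, or 1 dsRNA, differed by 0.17 to 0.92 within their pair. Of the 45 ways to pair the arrays within each treatment 3 gave a summed difference as small (exact p = 0.0667), in a test chosen after the values were seen.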
